A study of Caenorhabditis elegans with 2 samples.

How the data were processed

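ChIP-seq libraries of whole L4 larvae with an eGFP-tagged NHR-10 transgene were analysed as 1 group of 2 biological replicates, with the group and replicate number taken from the labels. The labels name a fragment size range of 150 to 350 bp. The authors' deposited lists are in narrowPeak format for the ce10 and ce11 builds, per the descriptions deposited with the files. For each build there was 1 list of peaks and background per replicate, 1 such list called on both replicates together, and 1 list called optimal after thresholding by the irreproducible discovery rate (IDR). Per those deposited descriptions, all lists of a build were derived with the same single control alignment. The peak caller, its version, the aligner and the IDR threshold are not given in the sources used here.

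Per the file headers and format, each deposited region has a start, an end, a summit and a signal value given by the authors, whose scale is not stated. The signal was used within lists only, to rank peaks and to compare medians and quartiles of groups of peaks. Levels were not compared between lists. The deposited −log10 q-value of the authors was the same, 3.43, in all 994 optimal peaks of ce11 and was not used to rank. The optimal peaks were the 994 regions of highest signal in the pooled list, 5.70% of its 17447 regions, so the authors' optimal list did not filter single regions on their support in each replicate. Most regions had a fixed width with the summit at the centre (424 bp in 93.1% of ce11 optimal peaks). The 2 repeated entries of each pooled list were counted once. The deposited lists hold no read counts, so the depth per sample, and the precision that follows from it, are unknown.

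Positions are 1-based. The ce11 build is WBcel235, and genes, transcripts and exons were taken from Ensembl release 115 and sequence from the matching reference genome. The ce10 lists were used for comparisons within ce10 only, and no coordinates were converted. Circular shifts of ce10 lists used the chromosome lengths of ce11, and no ce10 annotation was used. A promoter window ran from 1000 bp upstream to 200 bp downstream of a transcript start of a protein-coding gene, and a peak was assigned to each gene whose window held its summit. The windows covered 26.1% of the 6 chromosomes. Summits were classed as coding exon, 5' UTR, 3' UTR, other exon, intron or intergenic, in that order, by protein-coding genes.

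The comparisons were fixed before the data were examined. Replicates were compared by the share of the 994 strongest regions of replicate 1 that overlapped the 994 strongest of replicate 2 by at least 1 bp, against 1000 circular shifts along each chromosome, and by the Spearman correlation of signal over optimal peaks. Promoter shares were set against 1000 circular shifts of the summits in one-sided permutation tests. Shares per chromosome were set against protein-coding transcript starts with exact two-sided binomial tests. For 24 gene lists, the share of members with a peak was compared with all other protein-coding genes by Fisher's exact test, two-sided. All members of the lists were found in the annotation. Presence of 7 motifs within 50 bp of the summit was compared with an equally wide flank window of the same peak, centred 300 bp away on a randomly chosen side, by an exact McNemar test. All 6-mers were screened on I, II and III and tested on IV, V and X. Regions within 40 kb centred on nhr-10 and on unc-119 were counted against 1000 random windows. Benjamini-Hochberg adjustment was applied over chromosomes, gene lists, motifs and 6-mers, with a threshold of 0.05, and, as added after seeing the data, over the 8 locus tests of each window width. The p-values of replicate overlap, promoter shares and summit classes are unadjusted. The p-values over peaks and genes describe these 2 libraries and not variation between animals.

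Genes were named by a rule fixed beforehand. It took the genes at the 20 strongest peaks, nhr-10, unc-119, nhr-68 and nhr-114 whatever their values, every member of the propionate shunt list, up to 4 members with the highest signal of every other list, and the 5 strongest peaks in no promoter window. It gave 61 genes, of which 6 had no optimal summit in the promoter window.

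Alternatives covered the number of top regions, the overlap that counts as shared, the build, the promoter window, whole regions in place of summits, the 497 strongest peaks, each replicate alone, all biotypes, the background and assignment of genes, the motif window and flank, and the locus window. Restricting to peaks among the 994 strongest of both replicates, leaving out peaks with a MEX sequence and leaving out X were chosen after seeing the data, as were 2 further choices among ties in the match on GC content and 2 forms of the gene list test. The planned match on upstream distance used a doubled one-tailed permutation p; the added forms were the same match with the two-sided rule of Fisher's test, and the doubled p without matching. MEX, TCGCGCAGGGAG, is a sequence known from recruitment sites of the dosage compensation complex on X. A match allowed at most 2 mismatches within 100 bp of the summit.

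The statistics of the planned comparisons were tested on simulated data; the matches on GC content and on upstream distance and the counts of shared 36-mers were not. A planted overlap of 39.9% of 994 regions was recovered as 40.5%, and a planted Spearman correlation of 0.536 as 0.54. A ribosomal list of 78 genes bound at the observed rate was called in 100% of draws, and 0.217% of the other lists were called. An E-box planted at summits ranked 1 of 2080 6-mers, and 0 6-mers were called without it. The simulated summits were random positions, so this check does not cover the difference in GC content between real summits and flanks. A locus window with planted regions was called, and 3.0% of 200 random windows had a p under 0.05. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.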

Results

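Genome-wide binding of NHR-10, a nuclear hormone receptor known for its part in the switch to the propionate shunt when vitamin B12 is low, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole Caenorhabditis elegans larvae at the L4 stage, the last larval stage before adulthood. The worms belonged to strain OP239, which carries an inserted transgene for NHR-10 fused to eGFP in an unc-119 mutant background, and both sexes were pooled. The samples formed 1 group with 2 biological replicates, each sequenced as 1 technical replicate, and no second condition was compared. On the ce11 build the authors' list held 21319 regions for replicate 1 and 22317 for replicate 2. A further list from both replicates together held 17447 regions, and the optimal list, called optimal peaks here, held 994. Depth was unknown, because the lists give a signal per region and no read count. Intervals therefore cover only the sampling of peaks or genes. Bound means here only that a peak was called, since no other tagged factor and no control signal were analysed.

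The sites with the highest pooled signal ranked high in both replicates, as their choice by pooled signal favours. The site upstream of rpl-3, which encodes a protein of the large ribosomal subunit, had the highest pooled signal (333.1) and ranked 1 in replicate 1 and 2 in replicate 2. The site between nhr-68 and H12C20.7 ranked 8 and 9. NHR-68 is a nuclear hormone receptor that acts with NHR-10 on propionate shunt genes. A site in an intron of mom-1 on X ranked 3 in both lists, and the site between tasp-1, a protease gene, and K01G5.10 ranked 4 in both.

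Many optimal peaks were among the strongest regions of only 1 replicate. Of the 994 optimal peaks, 537 (54.02%, Clopper-Pearson 95% interval 50.9 to 57.2%) overlapped a region among the 994 strongest of both replicates, 208 only of replicate 1, 195 only of replicate 2 and 54 of neither. Of the 497 optimal peaks with the highest pooled signal, 435 overlapped such a region of both replicates and 0 of neither. All of the 100 with the highest pooled signal did so in both, which ranking by pooled signal favours. At single genes the ranks could differ widely, in examples chosen after the values were seen. The peak at cts-1, which encodes citrate synthase, ranked 1088 in replicate 1 and 108 in replicate 2, and the peak at elt-2, an intestinal transcription factor gene, ranked 4452 and 408. Conversely, the peak at col-176, a collagen gene, ranked 219 in replicate 1 and 2554 in replicate 2. Of the 994 strongest regions of replicate 1, 551 (55.4%) overlapped by at least 1 bp a region among the 994 strongest of replicate 2. The mean over 1000 circular shifts was 0.819% and the highest 1.91% (one-sided permutation p = 0.001, the smallest that 1000 shifts can give). The share hardly changed with the number of regions, at 55.8% for the 500 strongest and 54.6% for the 1988 strongest. Across the 992 optimal peaks with a region in both lists, the Spearman correlation of signal was 0.323 (permutation p = 1e-04, two-sided, the smallest that 10000 permutations can give). That correlation is across peaks, which are not independent replicates and were chosen by their pooled signal. Both replicates were called against the same control alignment, so part of the overlap may come from that control.

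**Figure D1:**
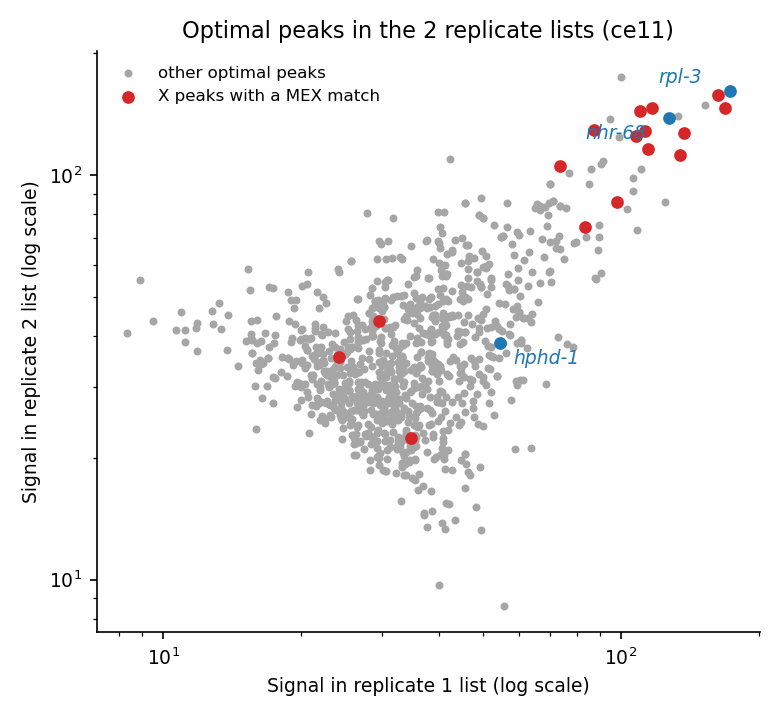
Signal of the optimal peaks in the replicate 1 list (horizontal, log scale) and the replicate 2 list (vertical, log scale). Each point is 1 peak of the 992 found in both lists; red points are X peaks with a match to the MEX sequence within 100 bp of the summit, and blue points are the peaks at rpl-3, nhr-68 and hphd-1. The Spearman correlation is 0.323 over peaks chosen by pooled signal.

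Optimal peaks were concentrated at promoters. Of the 994 optimal summits, 487 (49.0%, 95% interval 45.8 to 52.2%) lay between 1000 bp upstream and 200 bp downstream of a protein-coding transcript start, against a mean of 25.6% and a maximum of 29.6% over 1000 circular shifts (one-sided permutation p = 0.001). They marked 563 of 19973 protein-coding genes (2.82%), and 107 peaks lay in the windows of more than 1 gene. The highest was the rpl-3 site at III:3867436 to 3867706 on ce11, with an intergenic summit 271 bp upstream of the start. The 61 bp around that summit, III:3867553 to 3867613, read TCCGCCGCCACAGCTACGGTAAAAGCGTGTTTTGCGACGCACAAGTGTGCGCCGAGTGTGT. The tasp-1 and K01G5.10 site at III:10759129 to 10759397 had a signal of 301.9 and lay 41 bp upstream of tasp-1. The nhr-68 and H12C20.7 site at V:11572911 to 11573261 had a signal of 261.9, with the summit 355 bp upstream of nhr-68 and 95 bp upstream of H12C20.7. Its central 61 bp, V:11573055 to 11573115, read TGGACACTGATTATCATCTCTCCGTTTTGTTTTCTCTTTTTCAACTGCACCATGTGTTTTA. The other promoter sites among the 20 strongest peaks were upstream of nspc-17 on X, with a signal of 242.1, and between rpl-20 and Y17G9B.5 on IV, with a signal of 214.4.

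By annotation, 600 summits (60.4%) were intergenic, 256 (25.8%) intronic, 57 (5.73%) in 3' UTRs, 42 (4.23%) in 5' UTRs and 38 (3.82%) in coding exons. Coding exons held 24.3% of shifted summits and introns 33.2%, so both classes were bound less often than chance placement (permutation p = 0.001 each). Intergenic sequence held 37.5% of shifted summits, 5' UTRs 1.41% and 3' UTRs 3.38%, and these 3 classes were bound more often (permutation p = 0.001 each). The median distance from a summit to the nearest protein-coding start was 785.5 bp, and 669 of the 994 summits lay upstream of that start.

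Several of the strongest sites lay on the X chromosome far from any promoter. X held 13 of the 20 peaks with the highest signal, and 12 of these 13 were in no promoter window. The 5 strongest peaks outside promoter windows were all on X. The site at X:6296393 to 6296765 had a signal of 331.6 and lay in an intron of mom-1, 3409 bp upstream of cest-16, its nearest start. The intergenic site at X:11093967 to 11094372, nearest to W02H3.3 at 4000 bp, had a signal of 320.2. The next was at X:9465739 to 9466012, nearest to ZK899.6 at 2520 bp, with a signal of 276.8. The site at X:13700733 to 13701029 had a signal of 276.4 and lay 6016 bp upstream of K02D3.1. The site at X:16682002 to 16682247, nearest to F22H10.2 at 2566 bp, had a signal of 271.1.

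X held more optimal peaks than its share of protein-coding transcript starts, and chromosome V fewer. No other background, such as sequence length, was tested, and 142 of the 240 X peaks lay in no promoter window. X carried 240 of the 994 optimal peaks (24.1%, 95% interval 21.5 to 26.9%) but 14.04% of protein-coding transcript starts (exact two-sided binomial test, adjusted p = 1.28e-16). V carried 155 peaks (15.6%, interval 13.4 to 18%) and 23.5% of starts (exact adjusted p = 2.82e-09). III held 15.9% of peaks and 13.4% of starts (exact adjusted p = 0.038), and IV 14.4% and 17.5% (exact adjusted p = 0.0192). The test found no difference for I, with 13.6% of peaks and 14.8% of starts (exact adjusted p = 0.365), or II, with 16.4% and 16.8% (exact adjusted p = 0.799). The calls for III and IV were lost with the 497 strongest peaks alone (exact adjusted p = 0.13 and 0.0769) and with replicate 2 alone (exact adjusted p = 0.0845 and 0.0869). In promoter windows lay 98 of the 240 X peaks (40.8%, 95% interval 34.6 to 47.3%) and 389 of the 754 autosomal peaks (51.6%, interval 48.0 to 55.2%). Shifted summits lay there in 21.8% and 26.8%, so the enrichment was similar, at 1.87-fold on X and 1.92-fold on autosomes.

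**Figure D2:**
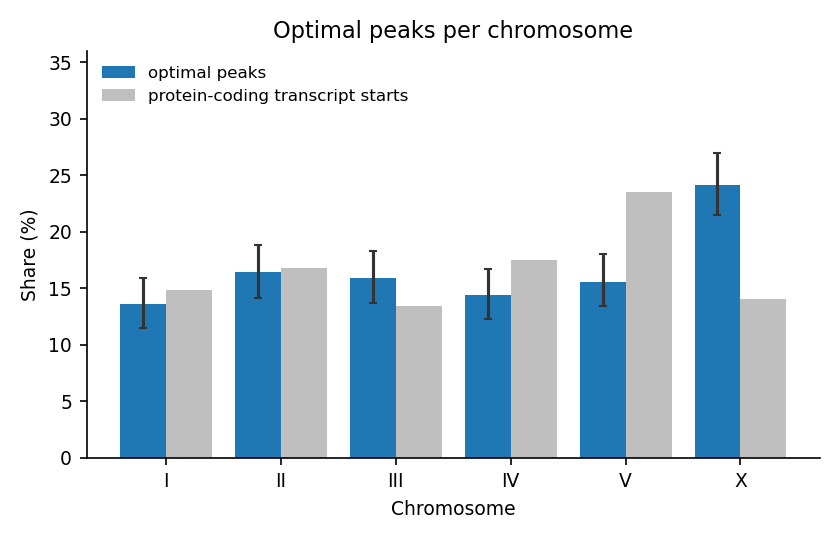
Share of the 994 optimal peaks (blue, with Clopper-Pearson 95% intervals) and of protein-coding transcript starts (grey) on each chromosome, in percent. X held 24.1% of peaks and 14.04% of starts, and V 15.6% and 23.5%.

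Genes for ribosomal proteins and heat shock proteins were bound more often than other genes. Of 78 cytosolic ribosomal protein genes, 18 (23.1%) had an optimal summit in the promoter window, against 2.74% of the other protein-coding genes (odds ratio 10.7, Fisher's exact test, adjusted p = 1.02e-10 over 24 lists). Besides rpl-3 and rpl-20 the strongest were rpl-35 (signal 184.5) and rpl-15 (157.7). Of 22 heat shock protein genes, taken as all genes with a symbol starting in hsp-, 5 were bound (22.7%, odds ratio 10.2, exact adjusted p = 0.00371). They included hsp-60, a mitochondrial chaperonin gene, with a signal of 130.5, the cytosolic chaperone genes hsp-1 (106.2) and hsp-90 (94.2), and hsp-3 (75.4), a chaperone gene of the endoplasmic reticulum. The hsp-60 peak also lay in the window of Y22D7AL.10, the hsp-90 peak in that of C47E8.4 and the rpl-15 peak in that of K11H12.8. With peaks assigned to the nearest start, 10 ribosomal protein genes were bound (12.8%, odds ratio 4.49), and the odds ratio of heat shock proteins was 6.74; with the 497 strongest peaks the latter was 19.9.

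The propionate shunt, the B12-independent route of propionate breakdown that NHR-10 is known to control, had peaks at 2 of its 5 genes (40%, odds ratio 23.1, Fisher's exact adjusted p = 0.045). This call was lost in 6 of 10 alternatives; with replicate 2 alone 1 gene was bound (odds ratio 9.01). The peak at hphd-1, the 3-hydroxypropionate dehydrogenase gene, lay at II:12996196 to 12996619 with a signal of 95.7 and ranked 164. Its summit lay 25 bp upstream of a transcript start and in an intron of a longer hphd-1 transcript. The 61 bp around it, II:12996378 to 12996438, read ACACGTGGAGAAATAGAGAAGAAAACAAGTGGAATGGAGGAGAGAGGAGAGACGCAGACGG. The peak at hach-1, which encodes a hydrolase of the pathway, lay at III:5554921 to 5555344, 317 bp upstream of its start, with a signal of 61.0 and rank 563; nmad-1 shared that window. No optimal peak lay in the windows of ech-6, alh-8 or acdh-1. In the pooled list the strongest region in the ech-6 window ranked 1427 and that in the alh-8 window 1678. The acdh-1 window held no region of the pooled list, and the optimal peak nearest to its start was 56615 bp away.

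The list named for the TCA and glyoxylate cycle was fixed beforehand and does not separate mitochondrial from cytosolic enzymes. It had peaks at 4 of 19 genes (21.1%, odds ratio 9.25, Fisher's exact adjusted p = 0.0138). These were cts-1 (signal 77.1), icl-1 (74.0), aco-1 (59.97) and idh-1 (57.4), which encode citrate synthase, the glyoxylate cycle enzyme isocitrate lyase and malate synthase, aconitase and isocitrate dehydrogenase. All 4 had a region in both replicates, ranked 1061 (aco-1) to 2397 (idh-1) in replicate 1 and 108 (cts-1) to 628 (aco-1) in replicate 2, so none was among the 994 strongest of replicate 1. The icl-1 peak also lay in the window of srh-2. Intestine markers had peaks at 3 of 16 genes (18.8%, odds ratio 7.99, exact adjusted p = 0.0455), namely the intestinal actin act-5 (65.3), the intestinal GATA factor elt-2 (57.1) and the aspartyl protease asp-1 (51.6). No peak lay at a marker of hypodermis and seam (13 genes), body wall muscle (13), pharynx (10) or neurons (15). None lay at the 6 vitellogenin genes either. These absences cannot show tissue specificity, because the lists are short and only 2.82% of other protein-coding genes were bound. The upper limits of the Clopper-Pearson intervals were 24.7% for hypodermis and seam, 24.7% for muscle, 30.8% for pharynx and 21.8% for neurons. That for vitellogenins was 45.9%. All lay above the 18.8% of intestine markers. With genes matched on upstream intergenic distance and a doubled one-tailed permutation p, the lists had 6.39 times the bound genes of matched draws for the TCA cycle (adjusted p = 0.0544), 11.9 times for the propionate shunt (0.0884) and 6.12 times for intestine markers (0.0884), and these 3 calls ended. Matching alone, with the two-sided rule of Fisher's exact test, kept all 5 calls (adjusted p = 0.0259 for the TCA list, 0.0492 for the shunt and 0.0492 for intestine markers). The doubled permutation p alone, without matching, ended those of the shunt and intestine markers (0.0832 each) and kept that of the TCA list (0.0464). The same 3 calls were lost with the 497 strongest peaks (exact adjusted p = 0.151 for the TCA list, 0.287 for the shunt and 0.509 for intestine markers). Their odds ratios there were 7.89, 16.7 and 4.46, with fewer peaks to test. With replicate 1 alone the TCA call was lost (2 of 19, odds ratio 4.07, exact adjusted p = 0.216). With replicate 2 alone those of the shunt (odds ratio 9.01, exact adjusted p = 0.214) and of intestine markers (odds ratio 5.16, exact adjusted p = 0.136) were lost. With peaks among the 994 strongest of both replicates no gene of the TCA list was bound, and the shunt (exact adjusted p = 0.243) and intestine markers (0.458) did not pass. The call for intestine markers was also lost in the window of 500 bp upstream (exact adjusted p = 0.119), and that for the shunt with peaks assigned to the nearest start (odds ratio 7.55, exact adjusted p = 0.278). Of 10 alternatives, the intestine call was lost in 6 and the TCA call held in 6. Intestine markers passed with replicate 1 alone (exact adjusted p = 0.038) and in the 2000-bp window (5 of 16, odds ratio 11.2, exact adjusted p = 0.00225). They also passed with the nearest start (6 of 16, odds ratio 18.3, exact adjusted p = 0.000156).

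The other lists did not pass the threshold with the planned window and all optimal peaks, though some did under alternatives. Of 10 alternatives, fatty acid synthesis passed in 6 (for example the 497 strongest peaks, odds ratio 12.6, exact adjusted p = 0.0181), vacuolar ATPase genes in 5 and nuclear hormone receptor genes in 5. Peroxisomal beta-oxidation passed with replicate 2 alone (odds ratio 12.1, exact adjusted p = 0.00871). The methionine/SAM list passed in the 2000-bp window (4 of 15, odds ratio 8.93, exact adjusted p = 0.00914) and with the nearest start (exact adjusted p = 0.0337). Branched-chain amino acid breakdown passed in the 500-bp window (exact adjusted p = 0.0446), and the acyl-CoA list with the nearest start (exact adjusted p = 0.015). Nuclear hormone receptor genes had peaks at 15 of 269 (odds ratio 2.06, Fisher's exact adjusted p = 0.0529), led by nhr-68, nhr-48 (83.9), nhr-105 (82.8) and nhr-32 (82.1). Fatty acid synthesis, elongation and desaturation had 3 of 19 (odds ratio 6.49, exact adjusted p = 0.0529), with elo-6 (79.9), fat-4 (74.1) and fat-6 (65.5). Vacuolar ATPase genes had 3 of 20 (odds ratio 6.11, exact adjusted p = 0.0533), with vha-1 (87.7), vha-12 (82.3) and vha-13 (70.0). Branched-chain amino acid breakdown had 2 of 9 (exact adjusted p = 0.0668), kat-1 (83.6) and bcat-1 (57.4). Acyl-CoA synthetases, dehydrogenases and mitochondrial beta-oxidation had 4 of 47 (exact adjusted p = 0.0937), acdh-9 (98.4), acs-2 (76.2), acs-17 (50.96) and acs-7 (49.97). UDP-glucuronosyltransferases had 5 of 67 (exact adjusted p = 0.0937), among them ugt-20 (90.4), ugt-49 (53.5), ugt-44 (52.0) and ugt-50 (51.5). The peaks at kat-1, vha-1, fat-6 and acdh-9 also lay in the windows of kars-1, sqv-3, ZK822.9 and F28A10.13, in that order.

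Of the methionine/SAM cycle and transsulfuration genes, 2 of 15 were bound (exact adjusted p = 0.131), ahcy-1 (78.1) and pmt-1 (60.9). Peroxisomal beta-oxidation had 2 of 16 (exact adjusted p = 0.135), dhs-28 (60.8) and acox-1.1 (54.3), and B12-dependent propionate breakdown 1 of 6 (exact adjusted p = 0.27), the propionyl-CoA carboxylase gene pccb-1 (56.2). Histone genes had 3 of 72 (exact adjusted p = 0.647), his-37 (81.9) and the pair his-61 and his-62 (50.9). Germline markers had 1 of 20 (exact adjusted p = 0.647), cgh-1 (49.7). Cuticle collagens had 2 of 156 (exact adjusted p = 0.532), col-93 (76.6) and col-176 (62.7). Cytochrome P450 genes had 1 of 74 (exact adjusted p = 0.967), cyp-13A2 (68.8), and glutathione S-transferases 1 of 44 (exact adjusted p = 1), gst-42 (72.4). The gst-42 peak also lay in the window of D1053.2. The 5 lists without a bound member had an exact adjusted p of 1 each. In simulated data, a list of 5 genes bound at 40% was called in 45% of draws, so lists of this size were often missed.

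**Figure D3:**
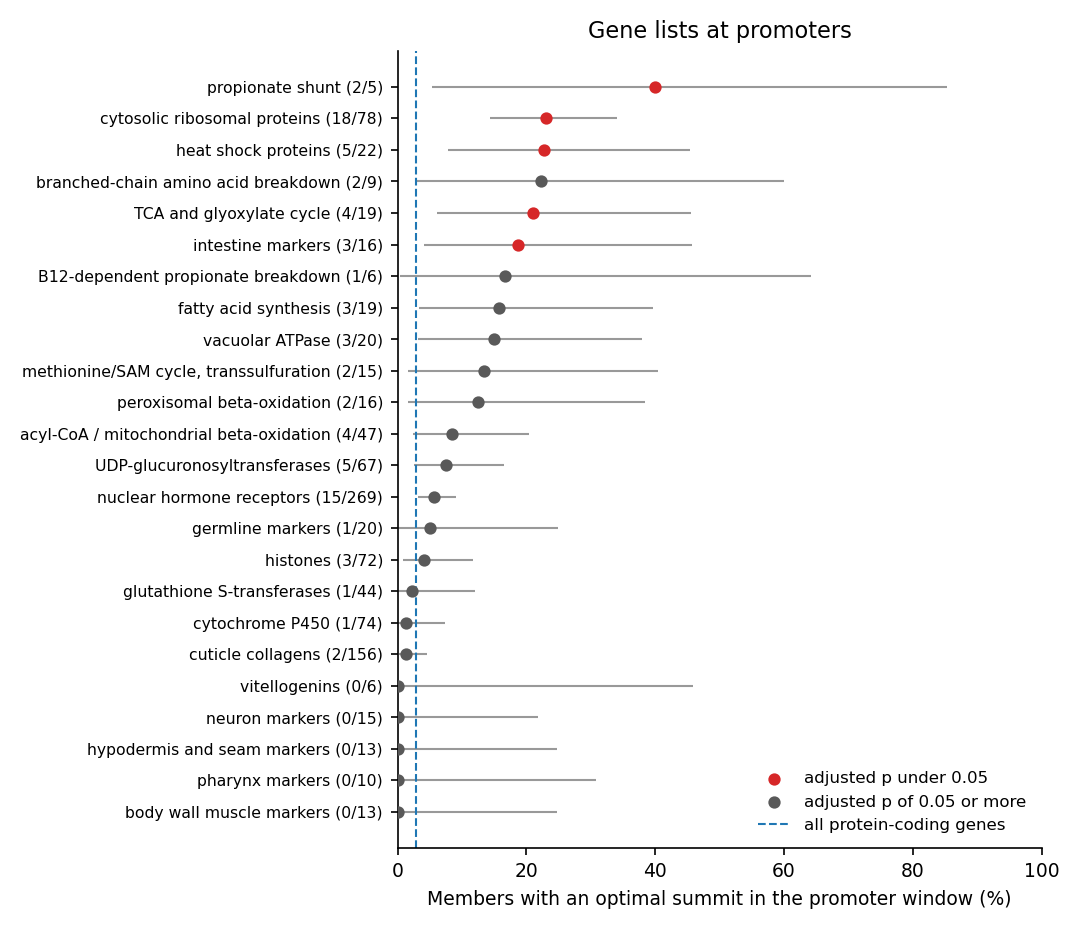
Share of each gene list's members with an optimal summit in the promoter window, in percent, with Clopper-Pearson 95% intervals (bound and tested members in brackets). Red marks an adjusted p under 0.05 and the dashed line all protein-coding genes (2.82%); ribosomal proteins stand at 23.1% and the propionate shunt at 40%, with a wide interval.

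Summits carried GAGA repeats, GATA sites, E-boxes and GC boxes more often than the flanks of the same peaks, and runs of T less often. GAGAGA occurred within 50 bp of 26.7% of summits and in 8.35% of equally wide flank windows centred 300 bp away (exact McNemar test, adjusted p = 1.82e-25, n = 994 peaks). The GATA site TGATAA, the sequence bound by intestinal GATA factors, occurred at 18.1% of summits and 9.05% of flanks (exact adjusted p = 1.06e-08). The E-box CACGTG stood at 7.95% and 2.82% (exact adjusted p = 6.52e-07) and the GC box CCGCCC at 6.14% and 1.91% (exact adjusted p = 1.96e-06). TTTTTT was found at 17.7% of summits and 38.3% of flanks (exact adjusted p = 6.48e-24), and TATAAA at 6.54% and 10.1% (exact adjusted p = 0.0064). The call for TATAAA was lost with the 497 strongest peaks and with replicate 1 alone (exact adjusted p = 0.227 and 0.313). The nuclear receptor half-site AGGTCA occurred at 3.52% of summits and 2.72% of flanks, a difference that did not pass the test (exact adjusted p = 0.366).

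The screen of 2080 6-mers on chromosomes I, II and III found 125 that were more frequent at summits and 98 that were less frequent. On IV, V and X, 88 of the 125 and 78 of the 98 passed again in the same direction. Among the former, AGAGAG stood at 22.3% of the 538 summits and 5.02% of flanks on IV, V and X (exact adjusted p = 2.9e-14). CGCAGA stood at 12.6% and 1.67% (exact adjusted p = 5.94e-12), AGACGC at 12.3% and 1.49% (exact adjusted p = 4.48e-11) and CGTCTC at 14.7% and 3.72% (exact adjusted p = 9.51e-09). Among the latter, AAAATT stood at 14.3% and 37.2% (exact adjusted p = 4.93e-15). GC content was 44.5% ± 8.57 at summits and 36.3% ± 8.79 at flanks (mean ± SD over the 994 peaks) and was higher at the summit in 738 peaks. The motif and 6-mer tests were not adjusted for this difference in base composition, so its part in most of their calls is unknown. A higher GC content alone would make TGATAA, mostly A and T, rarer at summits. Its 18.1% at summits against 9.05% at flanks argues against GC content alone for that call. The lower shares of TTTTTT, TATAAA and AAAATT go in the direction that GC content alone would give.

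**Figure D4:**
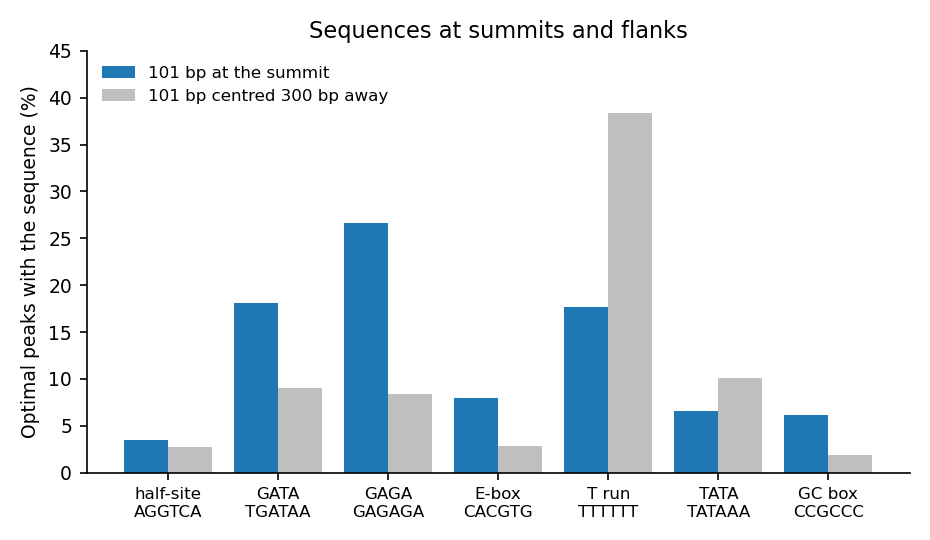
Share of the 994 optimal peaks with each sequence on either strand within 50 bp of the summit (blue) and in an equally wide window of the same peak centred 300 bp away (grey), in percent. GAGAGA stands at 26.7% and 8.35%, and TTTTTT at 17.7% and 38.3%.

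No list held an excess of regions around nhr-10 or unc-119 that passed Benjamini-Hochberg adjustment over the 8 tests of a window width. The 40 kb centred on nhr-10, III:7093866 to 7133865, held 10 regions of the pooled list, against a mean of 7.13 in random windows (one-sided permutation p = 0.282), 18 of the replicate 1 list (permutation p = 0.0729) and 11 of the replicate 2 list (permutation p = 0.342). It held 3 optimal peaks, against a mean of 0.448 (permutation p = 0.039, adjusted 0.292). The same 3 lay within 20 kb, against a mean of 0.193 (permutation p = 0.00999, adjusted 0.0799), and 4 within 80 kb, against 0.801 (permutation p = 0.038, adjusted 0.228). The strongest, at III:7116569 to 7116992, was intergenic with its summit 1343 bp upstream of the nhr-10 start, outside the promoter window. It had a signal of 107.4 and ranked 110, with rank 873 in replicate 1 and 46 in replicate 2. The 40 kb centred on unc-119, III:10885788 to 10925787, held 5 pooled regions (permutation p = 0.629) and no optimal peak; the strongest pooled region in the unc-119 promoter window ranked 11444. The receptor gene nhr-114, known for its part in control of the methionine/SAM cycle, had no optimal peak, and the strongest pooled region in its window ranked 1605. In a 20-kb window around nhr-10 the replicate 1 list held 12 regions (permutation p = 0.033, adjusted 0.132).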

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

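The overlap of replicates, the promoter share, the excess on X and the deficit on V, and the calls for ribosomal and heat shock proteins, GAGAGA, TGATAA, CACGTG, CCGCCC and TTTTTT kept their direction and their side of the threshold under every alternative run; the restriction to peaks among the strongest of both replicates, the omission of MEX peaks, the omission of X and the last 2 forms of the test over gene lists were chosen after seeing the data. For the chromosomes, no alternative changed the background of protein-coding transcript starts. Overlap ranged from 44.1% with summits within 100 bp to 55.8% with 500 regions. The promoter share ranged from 34.9% (shifts 11.7%) in the 500-bp window to 64.1% (shifts 45.8%) in the 2000-bp window. Chromosome III was no longer called with the strongest 497 peaks (16.1%), peaks supported in both replicates (15.6%) or the ce10 list (15.6%), nor IV with the strongest 497 (13.9%) or supported peaks (15.1%); over the replicates taken alone III ranged from 15.5 to 15.9% and IV from 14.4 to 15.3%, and I, at 12.5% in each, was called with replicate 1 alone. The number of gene lists past the threshold was 5, and became 3 for supported peaks, 9 in the 2000-bp window, 8 with the nearest start, 2 with matched genes and a doubled permutation p, 7 with matched genes and the two-sided rule of Fisher's test, and 3 with the doubled p and no matching, so the fall to 2 did not come from matching alone. The TATAAA difference was −2.41 points for the strongest 497 peaks and ranged from −2.62 to −1.41 over the replicates alone, and the AGGTCA difference was −0.186 for supported peaks and ranged from −0.101 to 1.21 over the replicates. Lists whose odds ratio crossed 1 were, for the strongest 497 peaks, B12-dependent propionate breakdown, peroxisomal beta-oxidation and germline markers (0 each), glutathione S-transferases (1.55) and histones (0.939). For supported peaks these were B12-dependent propionate breakdown, the TCA cycle and germline markers (0 each), glutathione S-transferases (1.57) and histones (0.949). In the 500-bp window they were glutathione S-transferases (1.14) and germline markers (0), and with the nearest start cytochrome P450 (1.73) and histones (0.861). Over the replicates taken alone the odds ratio ranged from 0 to 0 for germline markers, and from 0 to 6.91 for B12-dependent propionate breakdown, 0.471 to 1.52 for cytochrome P450, 0.801 to 2.64 for glutathione S-transferases, 0 to 3.00 for hypodermis and for muscle markers, 0.522 to 2.92 for UDP-glucuronosyltransferases and 0.985 to 2.70 for histones. None of these crossings passed the threshold on the other side, and the cause was not tested; fewer peaks enter with the strongest 497 and the supported sets. Of the 55 named genes with a promoter summit, 47 kept it in the replicate 2 regions alone, 42 in the replicate 1 regions alone and 35 among supported peaks. No paired analysis was possible because there is 1 group. Depth could not be weighed, because the lists hold no counts.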

Other observations

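Of the tests here, the counts near noncoding genes, the MEX sequence, the comparison of X with autosomal peaks and the match on GC content were chosen only after the results were seen. The rule for the comparison of X with autosomal peaks was replaced more than once after its result had been seen, and the match on GC content was redrawn after its first draw had favoured strong peaks among ties. Summits also gathered at genes for small noncoding RNAs. Within 200 bp of a tRNA, snRNA or snoRNA gene lay 57 of the 994 optimal summits (5.73%, Clopper-Pearson 95% interval 4.37 to 7.37%), against a mean of 0.542% over 1000 circular shifts (one-sided permutation p = 0.001). There were 19 at tRNA, 14 at snRNA and 25 at snoRNA genes. Outside promoter windows, the strongest autosomal peak, named here after the values were seen, lay at V:11824024 to 11824337 with a signal of 224.0, 1614 bp upstream of pyc-1, which encodes pyruvate carboxylase.

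X peaks away from promoters carried the MEX sequence TCGCGCAGGGAG or a close match more often than chance placement (13 of 142 in no promoter window, 9.15%, against at most 2.11% in shifts). Whatever their place, 13 of the 60 strongest X peaks (21.7%) had a match, all 13 among the 20 strongest, and 0 of the 60 strongest autosomal peaks; over all autosomal peaks 6 of 754 had a match (0.796%, against 0.316% in shifts, permutation p = 0.04). Judged by 36-mers alone, reads shared between repeats do not account for the matching X peaks. The median share of 36-mers with another copy in the genome was 0% over these 16 regions. Autosomal peaks matched on GC content at the summit had a median signal of 66.7, against 230.3. In 1000 further random draws among ties the median was at most 86.8. The upper quartile of each of these draws lay under 178.4, the lower quartile of the matching X peaks. The first draw took the strongest peak of each tie and so raised the match. It gave a median of 152.2 and an upper quartile of 194.5, and did not decide. Autosomal peaks of like GC content thus mostly had a lower signal. GC content is not excluded, because the choice among ties was changed after the first draw and the X peaks drew notice by their strength. A candidate explanation is signal at recruitment sites of the dosage compensation complex: 6.67% of the 240 X summits had a match, against at most 2.08% of shifted X summits (permutation p = 0.001). A raised background over the whole X stays open too: without the matching peaks X still held 23.05% of peaks against 14.04% of starts. The median signal of X peaks without a match was 64.4, hardly above the 63.5 of autosomal peaks. Signal medians of peaks past a common minimum cannot exclude a raised background, however. Whether NHR-10 itself binds there, or such sites give signal with any tagged factor, stays open, because no other factor and no control signal were analysed here.

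Peaks at ribosomal protein gene promoters may reflect signal that gathers at highly transcribed genes whatever the factor. The excess of summits near tRNA, snRNA and snoRNA genes (5.73% against at most 1.41% in shifted sets) goes with that explanation. Heat shock protein genes were also bound more often than other genes (5 of 22, odds ratio 10.2), which goes with it if they are highly transcribed. Cuticle collagens, taken as another strongly transcribed family, were not bound more often (2 of 156, odds ratio 0.446). This goes against that explanation only if collagens were highly transcribed in these larvae, which was not measured. Histones (3 of 72) did not pass the test. Body wall muscle markers (0 of 13) did not pass either but cannot decide, because their interval reached 24.7%, above the 23.1% of ribosomal protein genes. With lists on both sides, the explanation stays open. Judged by 36-mers alone, reads shared between paralogs or pseudogenes do not account for most of the peaks at ribosomal protein genes. The median share of 36-mers with another copy was 0% over the 18 peaks and 38.6% at most, in the only region over 20%. For that region shared reads are not excluded, and the reads themselves were not examined. Binding by NHR-10 at ribosomal protein genes stays open as well, since expression was not analysed here and no biological explanation was tested.

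Peaks around nhr-10 could come from extra copies of the inserted nhr-10 fragment. The 40-kb window held 10 pooled regions, above the median of 6 random regions but within their range (permutation p = 0.282), and its 3 optimal peaks, against a random mean of 0.448, did not pass after adjustment (permutation p = 0.039, Benjamini-Hochberg adjusted 0.292). Extra copies and binding at the native locus cannot be told apart, because neither the ends of the inserted fragment nor the strain of the control are given in the sources used here.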
